A study of Homo sapiens with 7 samples.

How the data were processed

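H3K4me3 ChIP-seq was done in HCT116 cells with both copies of KDM5A knocked out and transfected with an empty vector, wild-type KDM5A or mutant KDM5A. The series has 7 samples: 1 H3K4me3 library and 1 input library for each transfection, and 1 pooled IgG control. Per the labels' protocols, chromatin was crosslinked with formaldehyde and sheared by sonication to fragments of about 250 to 750 bp. Per the submitters' processing notes, the tools used upstream included Bowtie2 2.5.4, MACS, MACS2, HOMER and deepTools 3.5.6, and the genome build was hg19. How peaks were called (per library or on merged libraries), which duplicates were removed and how reads were counted are not given in the sources used here.

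The deposited table lists 30840 regions with the RPM (reads scaled to a library total of 1000000) of the 3 H3K4me3 libraries, as the authors computed it. The header of the empty vector column names H3K4me4, which was read as a slip for H3K4me3, the histone mark the labels give. The input and IgG libraries were not analysed here, so no background was subtracted and the planned comparison of ChIP with input and IgG was not made. RPM divides by the reads of a library and sets the 3 libraries to the same total, so that a loss of mark at all regions and a lower share of ChIP reads on target give the same values, and no spike-in was used here.

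Every RPM value was a whole multiple of 1 step per library, 0.0933 for the empty vector, 0.0921 for wild-type and 0.101 for mutant KDM5A, within 0.02 reads for 100% of values in each library. For comparison, a step of 0.1 gave whole multiples for 4.98%, 3.04% and 3.79% of values. Whole reads were recovered by dividing by the step, and 1000000 divided by the step gave the total reads, 10713021, 10852411 and 9906508. These reads were used for intervals and simulated counting noise. With 1 library per group no count model was fitted, and a test on reads would compare these libraries and not the conditions. A value of 0 reads allows up to 3 reads, which is 0.280, 0.276 and 0.303 RPM in the same order, and 164, 138 and 80 regions had 0 reads. PCR copies are not independent molecules, so intervals and floors cover counting error only.

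For each of 3 pairs of libraries the log2 ratio of RPM plus a pseudocount of 0.7 RPM (the 10th percentile of positive values, to 1 digit) was computed per region. This scale understates the change of weak regions. Folds of single regions and of the cluster are plain ratios of RPM without a pseudocount, with exact conditional (Clopper-Pearson) 95% intervals from the reads, and shares of reads have Wilson intervals. Regions past 1.5-fold on the log2 scale were counted. Before the data were examined, the pseudocount, the thresholds of 1.5-fold and 2-fold, the deciles and width classes, the alternatives and the rule for named regions were fixed. The rule took, for each comparison, the 8 highest and 8 lowest log2 ratios among regions at or above the median mean RPM (4.70), placed by coordinates where no annotation of the build was at hand. Chromosome Y was left out of the named regions and of the medians by chromosome. Chosen after the data were examined were the classes of strong (mean of 20 RPM or more), middle (5 to 20 RPM) and weak regions, the definition of the chromosome 12 cluster, the classes of width and distance among middle regions (2 kb, 100 kb) and the alternative without the cluster. The cluster holds each region with under 1 RPM with the empty vector between the first and last of 19 regions that also had more than 5 RPM with both forms of KDM5A.

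Counting noise was simulated in 100 draws: the mean profile of the 3 libraries, times 1 factor per library in each of 50 bins of mean RPM, was drawn as Poisson reads and put through the same steps, the pick of the most extreme regions outside the cluster included. The procedure was tested on simulated data for wild-type KDM5A against the empty vector, with 200 regions changed at a time. Among the 15109 regions of 5 RPM or more it recovered 99% of 2-fold and 100% of 4-fold changes at the 1.5-fold threshold, and 0.268% and 0.228% of unchanged regions passed it. Among the 15711 weaker regions it recovered 58% and 90.5%, and 8.38% and 8.44% of unchanged regions passed. Counts of weak regions past 1.5-fold are therefore set beside those of the simulated draws.

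The alternatives were pseudocounts of 0.07 and 3.5 RPM, regions at or above the median mean RPM, scaling to a median ratio of 1, scaling to equal sums over the regions, removal of a lowess trend on level (span 0.3), a 2-fold threshold and autosomes only. The RefSeq gene table used here is of GRCh38.p14, and on 14 of 23 chromosomes the regions reached beyond its last gene, so it gave no region a gene. For that reason the 17 gene lists fixed beforehand, the genes to be named in every case and the classes of place were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.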

Results

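H3K4me3, the trimethylation of lysine 4 of histone H3 that marks active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in HCT116 cells, a human colon cancer line, in which the KDM5A gene was knocked out. KDM5A is a demethylase that removes this mark. The knockout cells were transfected with an empty vector, with wild-type KDM5A or with a mutant KDM5A and fixed 24 h later. The title of the series concerns methylation of KDM5A by the lysine methyltransferase SMYD2 and its effect on demethylase activity, and the sources used here do not say which residues the mutant changes. Each transfection gave 1 H3K4me3 library, so the differences below have no replicate check and no p-value, and every interval covers counting error only. The 3 libraries were measured over the same 30840 regions, which span 49.4 Mb of hg19, have a median width of 1268 bp and carry values in RPM, reads scaled to a library total of 1000000. Their depth was 10713021 reads for the empty vector, 10852411 for wild-type KDM5A and 9906508 for mutant KDM5A. No region was matched to a gene, because the gene table used here is on another genome build, and regions are therefore named by chromosome, start and end.

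A cluster of 20 regions at chromosome 12, 394565 to 493388, was nearly empty in the empty vector library and strongly covered in both KDM5A libraries. Over the cluster the empty vector library held 43 reads (4.01 RPM), the wild-type KDM5A library 4297 reads (396 RPM) and the mutant KDM5A library 4825 reads (487 RPM). The summed signal was thus 98.6-fold higher with wild-type KDM5A (95% interval 73.1 to 137) and 121-fold higher with mutant KDM5A (89.9 to 168). The 8 highest ratios to the empty vector of each KDM5A library, among regions at or above the median mean RPM, all lay in this cluster. The region at 416074 to 417167 had 0.747 RPM with the empty vector, 79.98 RPM with wild-type KDM5A and 96.5 RPM with mutant KDM5A. The region at 401910 to 402345 had 0.280, 41.1 and 54.5 RPM in the same order. In 5 of the 20 regions the empty vector library had 0 reads, which allows up to 0.280 RPM (3 reads). Mutant KDM5A was above wild-type KDM5A in all 20 regions and 1.23-fold higher over their sum (1.18 to 1.28). The cluster's regions were narrow, with a median width of 290 bp. The next listed region, at 496602 to 499566 and 3213 bp beyond the cluster, had 55.1 RPM with the empty vector, 58.0 with wild-type KDM5A and 59.96 with mutant KDM5A. Both ratios to the empty vector there had intervals that include 1 (0.939 to 1.18 and 0.970 to 1.22). KDM5A itself is a chromosome 12 gene, and the gene table names no hg19 position for it.

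**Figure D1:**
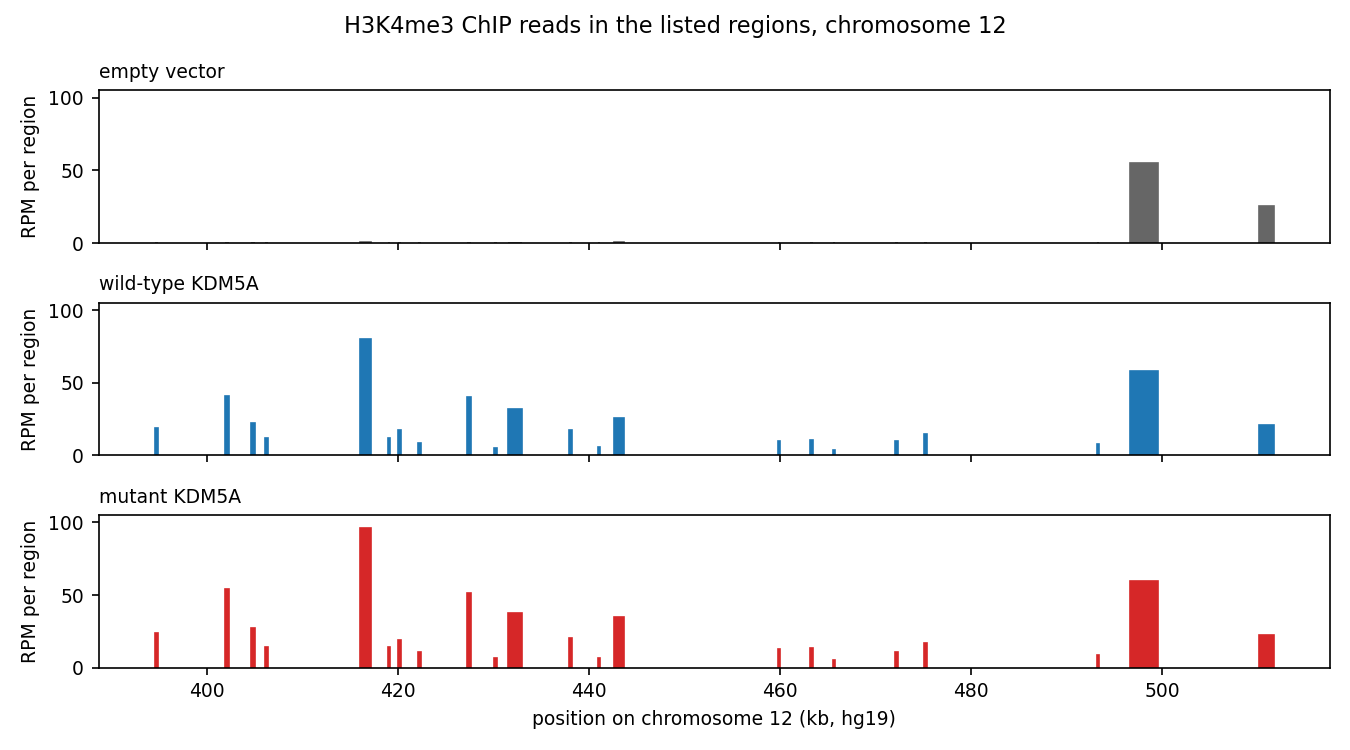
H3K4me3 ChIP reads in the listed regions at the start of chromosome 12, with the position in kb (hg19) on the horizontal axis and RPM per region on the vertical axis, 1 panel per library. Bars span the regions, with an outline that keeps narrow ones visible: the 20 narrow regions from 394565 to 493388 sum to 4.01 RPM with the empty vector, 396 RPM with wild-type KDM5A and 487 RPM with mutant KDM5A, while the pair of regions to their right is present in all 3 libraries.

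The first comparison asks whether putting wild-type KDM5A back into knockout cells changed H3K4me3. The listed regions held 67.0% of the reads of the empty vector library (Wilson 95% interval 67.01% to 67.07%) and 60.7% of those of the wild-type KDM5A library (60.67% to 60.72%), a change of −6.34 percentage points. Strong regions, the 10882 outside the cluster with a mean of 20 RPM or more, had a median log2 ratio of −0.15, a median change of −9.81%, and 91.4% of them were below 0. This shift was nearly uniform: the ratios had an SD of 0.11 on the log2 scale, against 0.092 from counting noise. At least 1.5-fold lower were 5 strong regions and 0 were higher, against simulated means of 0.37 and 0 (at most 2 lower in a draw). The region with the highest RPM, at chromosome 7, 5457539 to 5470144, had 279 RPM with the empty vector and 226 RPM with wild-type KDM5A. Of the strong regions, that at chromosome 9, 82185140 to 82189116, had the lowest ratio, with 37.1 RPM against 19.4 RPM (1.91-fold lower, 1.61 to 2.26), and that at chromosome 21, 28214161 to 28219231, followed with 30.8 against 18.4 RPM. The highest ratio of a strong region outside the cluster was at chromosome 11, 613777 to 616464, with 19.8 RPM against 29.9 RPM (1.51-fold higher, 1.26 to 1.80). With the pseudocount, which the counts past 1.5-fold use, it was 1.49-fold higher.

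Among the regions named by rule, the 8 lowest ratios of wild-type KDM5A to the empty vector were 2.38-fold to 3.14-fold lower. Regions named in this way were picked for extreme ratios and their intervals do not allow for that choice, so the same pick was made in the 100 simulated draws. There the lowest log2 ratio averaged −0.87 and reached −1.17, and the 8th lowest reached −0.76, while the observed ones were −1.44 and −1.14. The draws, here and below, held counting noise and no variation between library preparations. Ratios past them may therefore still come from such variation. The 8 lowest observed ratios came from regions of 8.31 to 14.9 RPM with the empty vector. The region at chromosome 1, 75600267 to 75603026, had 8.96 RPM with the empty vector and 2.86 RPM with wild-type KDM5A (3.14-fold lower, 2.07 to 4.87). On chromosome 18, the region at 31157559 to 31159561 had 14.9 against 5.81 RPM and that at 30350968 to 30352609 had 8.49 against 3.13 RPM. A chromosome 7 region, at 69062197 to 69065638, had 14.5 against 6.08 RPM. The other 4 lay at chromosome 2, 105471082 to 105474514 and 42274178 to 42276447, at chromosome X, 136647594 to 136651619, and at chromosome 5, 65891808 to 65893598. Outside the cluster and at or above the median mean RPM, the highest ratio was at chromosome 16, 70461798 to 70463046, with 2.71 against 6.27 RPM (2.31-fold higher, 1.48 to 3.71), a ratio that 1 of the 100 draws also reached. Also on chromosome 16, the region at 4992625 to 4996291 had 11.9 against 21.7 RPM (1.83-fold higher, 1.47 to 2.28). Strong regions and regions outside the cluster were singled out after their values were seen.

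Over all 30840 regions the median log2 ratio of wild-type KDM5A to the empty vector was −0.11 (quartiles −0.25 and 0.11), and 2015 regions were at least 1.5-fold lower and 1922 higher. Most of these were among the 15711 weak regions, below 5 RPM, with 1870 lower and 1872 higher and a median of 0. In 100 simulated draws with counting noise and no change particular to a region, the weak regions gave a mean of 650 lower and 705 higher, at most 716 and 759. Of the 4227 middle regions, from 5 to 20 RPM, 140 were lower and 30 higher, against simulated means of 27.1 and 3.49. The direction of the overall shift rests on scaling by each library's total reads. Scaling to a median ratio of 1 among the stronger regions moved the overall median by 0.13 to 0.024 and changed the split of regions past 1.5-fold from 51.2% lower to 36.7% lower.

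The second comparison asks the same of mutant KDM5A. The regions held 56.9% of its reads (56.92% to 56.98%), a change of −10.1 percentage points from the empty vector. Strong regions had a median log2 ratio of −0.24, a median change of −15.5%, and 98.1% of them were below 0. The SD of their ratios was 0.12, against 0.096 from counting noise, with 47 at least 1.5-fold lower and 0 higher outside the cluster. Simulated draws, which carry the shift of each level, gave means of 10.7 lower and 0 higher, and at most 19 lower. The lack of higher regions thus follows from the shift. The region at chromosome 9, 82185140 to 82189116, again had the lowest ratio of the strong regions, with 17.5 RPM under mutant KDM5A (2.12-fold lower than the empty vector, 1.77 to 2.55), and that at chromosome 21, 28214161 to 28219231, had 17.8 RPM. The region of highest RPM, at chromosome 7, 5457539 to 5470144, had 204 RPM.

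The 8 lowest named ratios of mutant KDM5A to the empty vector were 2.72-fold to 3.51-fold lower. Their log2 ratios ran from −1.67 to −1.28, where the lowest and the 8th lowest of the simulated draws went no further than −1.26 and −0.86. The lowest was at chromosome 16, 51183386 to 51187250, with 15.96 RPM for the empty vector, 7.46 for wild-type KDM5A and 4.54 for mutant KDM5A (3.51-fold lower than the empty vector, 2.52 to 5.00). The region at chromosome 21, 33244760 to 33246880, had 15.1, 9.68 and 4.64 RPM in that order, and that at chromosome 3, 55519408 to 55522435, had 10.9, 5.71 and 3.53 RPM. The region at chromosome 1, 75600267 to 75603026, was the 1 region among the 8 lowest under both forms of KDM5A, with 3.03 RPM for the mutant. This small overlap of the lists does not mean that different regions were lower. Each of the 8 regions named as lower with wild-type KDM5A also had less RPM with the mutant than with the empty vector. At chromosome 18, 31157559 to 31159561, for example, the mutant had 6.86 against 14.9 RPM. The other 4 lay at chromosome 4, 109087854 to 109090334, chromosome 2, 119602107 to 119605891, chromosome 6, 166074206 to 166078117, and chromosome 17, 71638966 to 71641341. Among regions outside the cluster and at or above the median mean RPM, the highest ratio was at chromosome 2, 33141308 to 33141755, with 2.99 RPM for the empty vector and 7.47 RPM for mutant KDM5A (2.501-fold higher, 1.63 to 3.91), followed by chromosome 12, 104996444 to 104998529, with 2.61 against 5.96 RPM.

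Over all regions the median log2 ratio of mutant KDM5A to the empty vector was −0.18 (quartiles −0.33 and 0.071), with 2512 regions at least 1.5-fold lower and 2040 higher. Weak regions made up 2184 and 1996 of these, against simulated means of 841 and 752. Of the middle regions 281 were lower and 24 higher, against simulated means of 93.3 and 1.6. Scaling to a median ratio of 1 moved the overall median by 0.22 to 0.035 and changed the split past 1.5-fold from 55.2% lower to 31.2% lower.

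The third comparison asks whether mutant KDM5A left another level of H3K4me3 than wild-type KDM5A. The share of reads in regions was lower with the mutant, a difference of −3.75 percentage points. Strong regions had a median log2 ratio of mutant to wild-type KDM5A of −0.093, a median change of −6.24%, with 79.7% of them below 0 and none past 1.5-fold in either direction outside the cluster. A ratio as low as the lowest of a strong region was held by 42 of 100 simulated draws and one as high as the highest by 5, while the 8th lowest was reached in 1 draw and the 8th highest in 0. The lowest was at chromosome 11, 31829968 to 31834661, with 40.4 RPM for the empty vector, 37.4 for wild-type and 25.0 for mutant KDM5A (1.49-fold lower than wild-type, 1.27 to 1.76). The highest was at chromosome 1, 52082265 to 52084204, with 44.2, 35.2 and 46.6 RPM (1.32-fold higher, 1.15 to 1.52).

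Among the regions named by rule, the 8 lowest ratios of mutant to wild-type KDM5A were 1.74-fold to 2.08-fold lower. These lay within what picking extremes from counting noise gave, since the lowest ratio was matched or passed in 33 and the 8th lowest in 21 of 100 simulated draws. The region at chromosome 21, 33244760 to 33246880, had 9.68 RPM with wild-type and 4.64 RPM with mutant KDM5A (2.08-fold lower, 1.46 to 3.01). On chromosome 8, the region at 27218834 to 27220306 had 7.92 against 3.84 RPM, that at chromosome 11, 76381220 to 76382100, had 9.49 against 4.95 RPM, and that at chromosome 13, 113597191 to 113598638, had 13.5 against 7.37 RPM. The other 4 lay at chromosome 1, 210465502 to 210467011, 28574802 to 28576731 and 6530987 to 6532528, and at chromosome 7, 25010030 to 25012229. The 8 highest were 1.66-fold to 1.92-fold higher with the mutant, and 28 draws held a ratio as high as the highest, while 0 draws had an 8th highest as high as the observed one. On chromosome 10, the region at 128946104 to 128947889 had 3.41 RPM with wild-type and 6.56 RPM with mutant KDM5A (1.92-fold higher, 1.27 to 2.96), and that at chromosome 1, 68165236 to 68167061, had 3.87 against 6.97 RPM. The other 6 lay at chromosome 2, 96925857 to 96927238, chromosome 9, 132040244 to 132041523, chromosome 17, 41916963 to 41918435 and 25706990 to 25708175, and chromosome 10, 69853362 to 69855337 and 123900227 to 123901700.

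Over all regions the median log2 ratio of mutant to wild-type KDM5A was −0.077 (quartiles −0.23 and 0.089), with 1682 regions at least 1.5-fold lower and 1601 higher. Weak regions made up 1602 and 1583 of these, against simulated means of 794 and 722. Of the middle regions 80 were lower and 18 higher, against simulated means of 34.8 and 4.47 (at most 56 and 10 in a draw). Scaling to a median ratio of 1 gave an overall median of 0.0089 and, of the regions past 1.5-fold, 41.7% lower in place of 51.2%.

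The ratios followed the strength of the regions. In the weakest decile of mean RPM the median log2 ratio to the empty vector was −0.0022 for wild-type and 0.059 for mutant KDM5A, and in the strongest decile it was −0.15 and −0.25. From the seventh decile up the medians hardly changed, at −0.14 and −0.24 in that decile. Regions under 1 kb had medians of −0.0039 and −0.0077, those of 1 to 2 kb −0.095 and −0.18, those of 2 to 4 kb −0.15 and −0.24, and those over 4 kb −0.16 and −0.26. By chromosome, with Y left out, the median of the strong regions ran from −0.19 on X to −0.12 on 13 for wild-type KDM5A. For mutant KDM5A it ran from −0.27 on 21 to −0.22 on 8. All 23 chromosomes compared thus shifted in the same direction under the authors' scaling. With a smooth trend of the ratio on level removed, the difference between the strongest and the weakest decile changed sign, from −0.15 to 0.043 for wild-type and from −0.31 to 0.021 for mutant KDM5A, since that step takes out the trend itself.

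**Figure D2:**
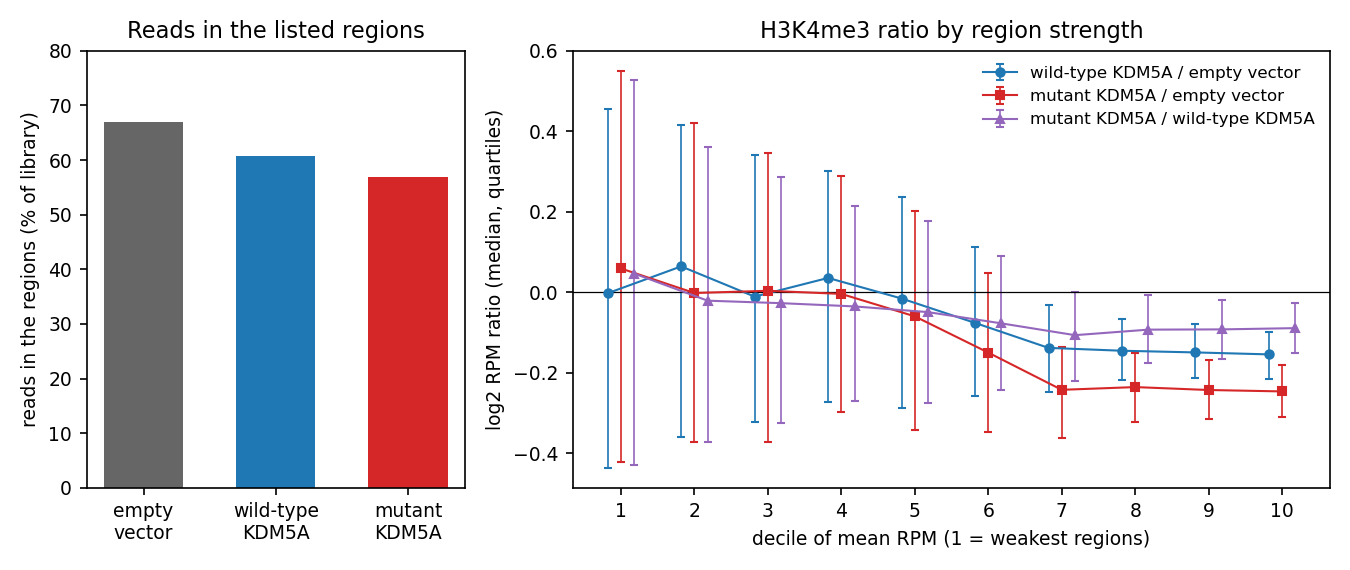
Left, bars of the percentage of each library's reads that fell in the 30840 regions: 67.0% for the empty vector, 60.7% for wild-type KDM5A and 56.9% for mutant KDM5A. Right, the median log2 RPM ratio (points, with bars from the lower to the upper quartile) against the decile of mean RPM for the 3 pairs of libraries, where both ratios to the empty vector lie near 0 in the weak deciles and reach −0.15 and −0.25 in the strongest.

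The responses to the forms of KDM5A were compared across regions, with the cluster left out; regions are not replicates, and both ratios share the 1 empty vector library. Middle regions lower in both by 1.5-fold numbered 100, where the simulated draws gave a mean of 4.23 and at most 9, and lists drawn independently would share 9.31. Higher in both were 13 middle regions, also more than in the draws, which gave a mean of 0.3 and at most 2, with 0.17 for independent lists. Across the 4227 middle regions Pearson's r between the ratios was 0.663 and Spearman's rho 0.598, against simulated means of 0.485 and 0.461, and the covariance was 0.0505 against 0.0189, a difference of 0.0316. Across the strong regions r was 0.485 against 0.458 and rho 0.450 against 0.438, with a covariance of 0.00638 against 0.00406. Over all regions outside the cluster r was 0.612 and rho 0.582 (simulated 0.532 and 0.489), the covariance 0.0940 against 0.0415, and 1171 regions were lower in both and 610 higher in both (simulated 141 and 208, independent lists 164 and 125). Part or all of any excess may come from the shared empty vector library, which cannot be split. Among middle regions the SD beyond counting noise was 0.18 and 0.20 for the ratios of wild-type and mutant KDM5A to the empty vector. It was 0.11 for mutant to wild-type KDM5A, which leaves that library out.

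**Figure D3:**
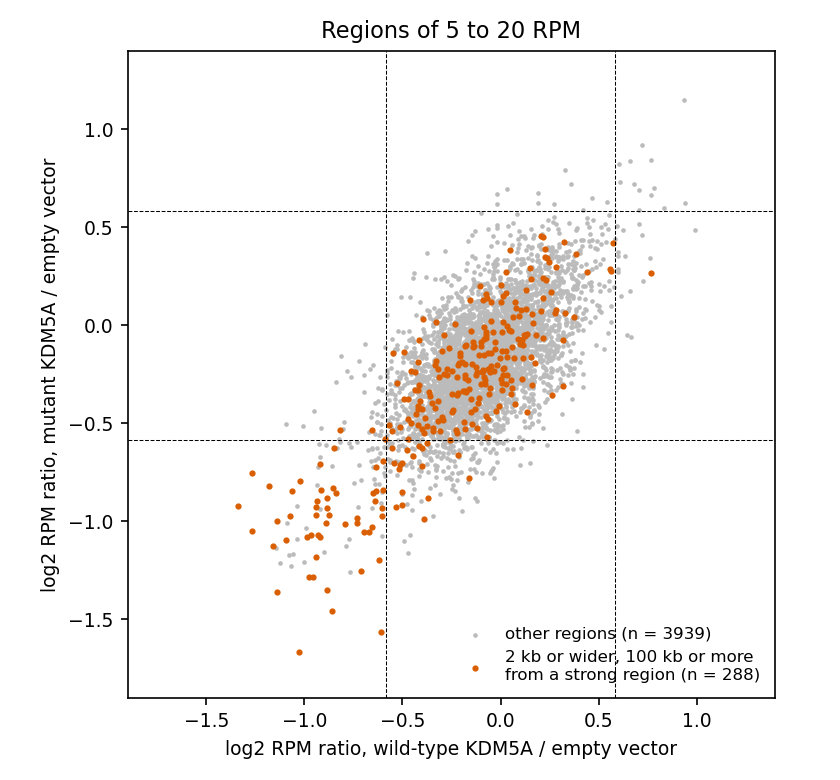
Log2 RPM ratio to the empty vector of wild-type KDM5A (horizontal) and mutant KDM5A (vertical) for the 4227 regions with a mean of 5 to 20 RPM, 1 point per region, with dashed lines at 1.5-fold. Orange points are the 288 regions at least 2 kb wide and at least 100 kb from a strong region, which make up 50 of the 100 points below both lower lines.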

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

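The alternative without the chromosome 12 cluster was chosen after seeing the data. Under the authors' scaling, the 3 median ratios stayed negative at or above the median mean RPM, on autosomes only and without the cluster. A pseudocount cannot change the sign of a region's ratio, so the other pseudocounts did not test the sign of the medians. The filter keeps the stronger regions, which carry the shift. The counts past 1.5-fold moved with the pseudocount and the filter because they are mostly weak regions. Values follow in the order wild-type KDM5A against empty vector, mutant KDM5A against empty vector, and mutant against wild-type KDM5A. With a pseudocount of 0.07 RPM the medians were −0.12, −0.20 and −0.084, with 3506 lower and 3552 higher, 3998 and 3581, and 3355 and 3006; r between the responses was 0.585, 2037 regions were lower in both, and the strongest minus the weakest decile was −0.14 (wild-type) and −0.35 (mutant). With a pseudocount of 3.5 RPM the medians were −0.080, −0.13 and −0.056, with 186 lower and 42 higher, 298 and 36, and 15 and 2; r was 0.706, 114 were lower in both, and the mutant's decile difference was −0.26. At or above the median mean RPM the medians were −0.14, −0.23 and −0.092, with 171 lower and 55 higher, 364 and 53, and 91 and 21. There r was 0.785 and 124 were lower in both, fewer regions being tested. That r includes the chromosome 12 cluster. At 5 RPM or more without the cluster r was 0.615, against a simulated mean of 0.490.

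Both other scalings turned the sign of the medians, which follows from their construction, since they set the stronger regions or the sums equal. Scaled to a median ratio of 1, the medians were 0.024, 0.035 and 0.0089, mutant KDM5A had 1547 lower and 3409 higher against the empty vector, r was 0.611, 753 were lower in both, and the decile differences were −0.063 and −0.20. Scaled to equal sums, they were 0.023, 0.031 and 0.0062, with 1553 and 3354 for the mutant, r of 0.611, 754 lower in both, and decile differences of −0.063 and −0.20. With the lowess trend removed the medians were −0.00065, −0.00078 and −0.00027, r was 0.627, and the decile differences changed sign to 0.043 and 0.021, since the step removes that trend. At 2-fold there were 398 lower and 322 higher, 549 and 363, and 200 and 269, with 159 lower in both. Without the cluster r was 0.612 in place of 0.642, and no median, count or decile difference moved past its limit; the same held for autosomes only.

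Each of the 48 ratios of regions named by rule was recomputed with both other pseudocounts, which cannot change the sign of a ratio. Of these alternative values, 71 stayed within the counting interval and 25 moved outside it. Depth limits what single regions can show: the share of 2-fold changes recovered in simulated data was 99% at 5 RPM or more and 58% below. Input subtraction, promoters only, the classes of place, the 3 alternatives for gene lists and the comparison with input and IgG were not run, for want of those columns or of an hg19 annotation in what was used here. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group has 1 library.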

Other observations

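All tests in this part were chosen after the results were seen. The 100 middle regions lower in both KDM5A libraries lay on 23 chromosomes and differed in width and place from the other middle regions. Their median width was 2387 bp against 1543 bp for all middle regions, and their median distance to the nearest strong region was 200 kb against 42.6 kb. Regions at least 2 kb wide made up 67% of them and 24.8% of all middle regions, and regions at least 100 kb from a strong region 61% and 28.0%. Of the 288 middle regions that were both wide and far, 50 (17.4%, exact interval 13.2% to 22.2%) were at least 1.5-fold lower in both. The interval does not allow for the cuts having been chosen after the data were examined. The shares were 2.23% of 761 wide regions near a strong one, 1.23% of 895 narrow distant ones and 0.964% of 2283 narrow near ones. The median ratio of the 100 regions was −0.84 with wild-type and −0.92 with mutant KDM5A, and mutant KDM5A was below wild-type in 65 of 100, much like the 65.8% of all middle regions. The densest run was at chromosome 12, 54331832 to 54434357, where 4 of 6 middle regions were lower in both. The run was chosen for those regions, and all 6 summed to 71.7 RPM with the empty vector, 45.0 with wild-type and 42.3 with mutant KDM5A, while 3 strong regions inside the run had log2 ratios of wild-type KDM5A to the empty vector from −0.27 to 0.0083.

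The first pattern weighed is the chromosome 12 cluster, gained in both KDM5A transfections. H3K4me3 newly placed on the chromosome is argued against by the width of these regions, a median of 290 bp against a 1st percentile of 652 bp among 14557 regions of similar RPM. A candidate explanation is reads from the transfected KDM5A cDNA, aligned to the exons of KDM5A, which is a chromosome 12 gene. A single source would keep wild-type and mutant reads in 1 ratio over the 20 regions, and the chi-square was 5.97 on 19 degrees of freedom, but this leaves it open, since only 24.9% of 1000 sets of other regions with like reads were uneven (p under 0.05, median chi-square 24.6) and whether the regions coincide with exons was not tested. If plasmid reads are the source, the 1.23-fold higher sum with mutant KDM5A may reflect more construct in those cells, which would leave dose and mutation mixed in the comparison of mutant with wild-type KDM5A. The sum does not measure dose alone, since the listed regions held 56.9% of the mutant library's reads and 60.7% of the wild-type library's.

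The second pattern is the lower RPM of strong regions. Other reads diluting every region by 1 factor are argued against, because the summed RPM of the 4 weakest deciles had a log2 ratio of 0.0077 for wild-type KDM5A (−0.0022 to 0.018) and −0.0095 for mutant KDM5A (−0.020 to 0.00059), where the strong regions' sums gave −0.15 and −0.25. These sums average unlike shifts. By decile, from the weakest up, mutant KDM5A gave 0.13, 0.023, −0.041 and −0.038, and wild-type KDM5A 0.047, 0.030, −0.0079 and −0.00069. Lower enrichment of the ChIP and a uniform loss of H3K4me3 cannot be told apart: both lower strong regions by nearly 1 factor, and the spread beyond counting noise was small, with an SD of 0.061 for wild-type and 0.070 for mutant KDM5A. KDM5A activity, the difference the design names, stays open and untested, since 1 library per group and no spike-in keep the explanations mixed.

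The third pattern is the loss at wide middle regions far from strong ones. For the middle regions as a whole, counting noise alone is argued against. There 100 were lower in both, and the highest of 100 simulated draws gave 9. The class itself had 50 against 2, but its cuts were chosen after the data were examined. The draws did not repeat that choice. The class median was less distinct: it was −0.18 (−0.22 to −0.13) with wild-type and −0.29 (−0.34 to −0.24) with mutant KDM5A, against level-matched simulated medians of −0.11 and −0.20, −0.14 (−0.17 to −0.13) and −0.22 (−0.24 to −0.20) for narrow distant regions and −0.018 and −0.090 for wide near ones. Both class intervals include the log2 ratios of the strong regions' sums, −0.15 with wild-type and −0.25 with mutant KDM5A. In this class 53 regions were at least 1.5-fold lower with wild-type and 68 with mutant KDM5A. Lowering each by the factor of the strong regions gave at most 8 and 21 in 100 draws. These counts pass counting noise around 1 factor. They leave lower enrichment of the ChIP open, since the draws held no variation between library preparations. Narrow near regions also passed their level-matched draws, with 49 lower with wild-type (at most 25) and 107 with mutant KDM5A (at most 68). An empty vector library that was high there by chance of its preparation stays open, because the ratio of mutant to wild-type KDM5A, which leaves that library out, was −0.11 (−0.15 to −0.080), no lower than the other classes beyond their intervals, and KDM5A activity stays open and untested, as replicate empty vector libraries would be needed to separate them.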
